A study of Mus musculus with 2 samples.

How the data were processed

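H3K4me1 was measured by chromatin immunoprecipitation and sequencing in heart tissue of embryonic day 12.5 mice, in 2 biological replicates that form 1 group. The replicates came from separate tissue samples, and male and female embryos were pooled. The labels give a fragment size range of 300 to 500 bp for both libraries. The analysis started from 4 deposited peak lists on mm10: 1 for each replicate, 1 for the pooled libraries, and a replicated list. Every peak of the replicated list is a peak of the pooled list, and per the notes deposited with the libraries it was derived from the other 3 lists. The deposited lists give for each peak the enrichment over control (fold, a ratio), and the −log10 p and −log10 q of the authors' peak caller, with the summit as an offset in bp. The peak caller, its version and threshold, and the read depth were not given in the sources used here. The lowest −log10 p was 2.00 in each replicate's list, and 98.6% of replicated peaks had a −log10 q of at least 2 and 76.4% of at least 5. The notes name an input file for replicate 1 and for the pooled list that they do not name for replicate 2, and whether the lists of both replicates were made in the same way was not stated. Without read counts the depth of each sample was unknown, no confidence interval was computed, and the spread between the 2 replicates is the only measure of precision. It holds for the replicates' own lists, and an SD of 2 values is itself uncertain. The deposited signal tracks and the control experiment were not used here.

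Peaks on the 21 chromosomes were kept, which left out 1 peak each from the replicate 2, pooled and replicated lists. Genes came from the GENCODE mouse release M21 annotation of GRCm38 (55413 genes, of which 21938 are protein-coding), with the 21911 protein-coding genes on these chromosomes used in the comparisons. The 244 assembly gaps of at least 1000 bp were left out of random placements and of densities per Mb. Coordinates in the text count from 1.

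The share of peaks of a replicate that overlapped the other list by at least 1 bp, and the Jaccard index of covered bases, were compared with 100 random circular shifts of replicate 2's peaks within chromosomes. Locations were assigned by the summit in the order promoter (within 1 kb of a protein-coding start site), exon, intron and intergenic, and compared with 100 shifts. The start site profile is the percent of bases under a peak in each 250 bp bin, strand-aware, to 5 kb on both sides of protein-coding start sites, and the value at the start is the mean of the bins on its 2 sides.

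For gene lists, the percent of each gene's domain (the gene and 10 kb on both sides) covered by peaks was computed. The median of a list was given as a percentile among 10000 random lists of the same size, matched on domain length in 20 bins. A percentile of at least 95 was called high and of at most 5 low, when the replicated list and both replicates' lists gave the call, and at these thresholds 2.1 of 21 lists pass by chance. All listed symbols were found in the annotation. The list of anterior Hox genes holds members of the A, B and D clusters.

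For motifs, 20 consensus sequences were sought on both strands in windows of 500 bp at 20000 summits drawn from the 152919 distal peaks (over 2.5 kb from a protein-coding start site). Control windows were matched on chromosome, GC content and repeat share, and lay at least 1000 bp from any pooled peak. A consensus was called high or low when its ratio lay outside that of 10 scrambles of its letters, and was not tested with fewer than 20 control windows matched or too few usable scrambles. For chromosomes, Pearson and Spearman correlations across 19 autosomes were tested with 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over the 3 lists.

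The lists, thresholds, main tests, main settings and most alternatives were fixed before the data were examined, and so was the rule for naming genes. The rule took 8 heart genes in every case, the 3 highest members and the lowest of each heart list by cover, and the highest and the lowest member of each other list. It also took the 10 genes of highest cover, the 5 peaks of highest enrichment, and the 5 widest regions after joining peaks at most 1 kb apart. The alternatives were the pooled list, each replicate's own list, −log10 q of at least 2 or 5, and other rules of overlap. They also took in other promoter distances, positions, gene sets, domains, matching and window choices. Scrambles with the same number of CpG, and lists without members whose domains overlap each other, were added later. So were the tests of gene density on X and of the share of cardiomyocytes. The genes named on X and the comparison of transcription factors with other genes were also chosen later. The design has 1 group, so no test between groups was possible.

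The methods were tested on simulated data with known answers. Of 200 unchanged random lists of 15 genes, 4.5% were called high and 5.5% low. When the cover of the listed genes was multiplied by 2, 50% of lists were called high, and by 4, 86.5%, so that a list of this size with a change below these sizes would often be missed. These rates are for cover by the replicated list alone. A call that also needs both replicates' lists can be no more frequent. Planted overlaps of 25.1%, 49.9% and 75.0% were measured at those values. The shared peaks were exact copies and the others were placed apart, so this checks the counting alone. Motifs of 3 families planted in 20% of 4000 windows of random sequence were each called high, and of the 14 others at most 2 were. The planted motifs had ratios of 4.34 to 17.4, above those found in the data. The test therefore does not show how often smaller ratios would be called. Computations used python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.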

Results

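Monomethylated histone H3 (H3K4me1), a mark of enhancers and of the flanks of active promoters, was mapped by chromatin immunoprecipitation and sequencing in heart tissue of B6NCrl mouse embryos at embryonic day 12.5, with male and female embryos pooled. The series held 1 group of 2 biological replicates, each from its own tissue sample, and no other tissue, stage or treatment. The labels name no question beyond where the mark lies in the heart at this stage. The list of replicate 1 held 241867 peaks and that of replicate 2 held 247304, a mean of 244586 ± 3845 (SD, n = 2). They covered 131 Mb and 126 Mb of the mm10 genome. The replicated list, which holds the peaks of the pooled libraries that the authors kept after comparing both replicates, held 185786 peaks over 137 Mb, or 5.17% of the sequence outside assembly gaps. Its peaks had a median width of 523 bp and a median enrichment over control of 3.16-fold. The depth of the libraries was not known, since the lists carry no read counts, so no counting interval was attached to any share. Values below are from the replicated list unless a replicate is named, and each SD is over the 2 replicates' own lists. The SD does not give the precision of the replicated list's value, which can lie outside both replicates.

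The first comparison asked how far the 2 heart samples marked the same regions. Of the peaks of replicate 1, 73.8% overlapped a peak of replicate 2, and 75.1% of those of replicate 2 overlapped one of replicate 1. The mean was 74.4%. These are the 2 directions of 1 comparison, so the difference between them is no measure of precision. Peaks of replicate 2 shifted at random along their chromosomes were overlapped by 9.19% of replicate 1's peaks at the median of 100 shifts and by 9.86% at most. The base-pair Jaccard index of the lists was 0.563, against 0.0300 in the highest shift. Regions of strong enrichment were nearly always shared: 95.7% of the top quartile of peaks in replicate 1 and 96.2% in replicate 2 had a partner, against 54.5% and 58.2% of the bottom quartile. Peaks of replicate 1 that were shared had a median of 3.15-fold and 446 bp, and those that were not had 2.61-fold and 240 bp. In replicate 2 the shared peaks had a median of 3.18-fold and 417 bp, and the others had 2.63-fold and 233 bp. Across 121021 pairs of peaks that overlapped each other alone, enrichment in the 2 replicates had a Spearman correlation of 0.493, which is across peaks, and peaks are not independent replicates. When a pair had to overlap by at least 50% of both peaks, the shared share was 48.9%.

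The replicated list took 63.9% of the 290587 peaks of the pooled libraries, and these were the stronger and wider regions, with a median of 3.16-fold and 523 bp against 2.29-fold and 212 bp for the peaks left out. Of the 140317 pooled peaks covered over at least 50% of their length in both replicates, 140304 were in the replicated list. The list also held 45482 peaks that were not covered to that extent in both, of which 23791 were so covered in replicate 1 alone, 18717 in replicate 2 alone and 2974 in neither. The share of replicated peaks covered over at least 50% of their length in both replicates was 75.5%. It was 39.7% when every list was limited to peaks with a −log10 q of at least 5. That limit kept 76.4% of replicated peaks but only 40.1% and 41.2% of the peaks of replicates 1 and 2.

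In the embryonic heart the mark lay mostly away from promoters and inside genes. By the position of its summit, 54.9% of peaks were in introns, 30.7% between genes, 9.52% within 1 kb of the start site of a protein-coding gene and 4.89% in exons. The distal peaks, more than 2.5 kb from any such start site, numbered 152919, or 82.3% of all. The median distance to the nearest start site was 20.2 kb, and 15.2% of peaks lay more than 100 kb away. Promoters nevertheless held 3.64 times the share that random shifts gave (2.61%, range 2.39% to 2.87% in 100 shifts), introns 1.52 times (36.2%) and exons 1.501 times (3.26%), while sequence between genes held 0.530 times its share (57.9%). The replicates' own lists gave 8.79% ± 0.0579 for promoters, 54.8% ± 0.136 for introns, 4.92% ± 0.0967 for exons and 31.4% ± 0.0181 between genes (SD, n = 2). All 4 shares were outside the range of the shifts in each replicate. Promoter peaks had the highest median enrichment, 3.25-fold, against 3.21-fold in introns, 3.14-fold in exons and 3.05-fold between genes. Promoter peaks were also above intergenic ones in replicate 1 (3.06-fold against 2.86-fold) and in replicate 2 (3.09-fold against 2.93-fold).

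Around the start sites of 21911 protein-coding genes the mark flanked the start and was lower on it. In the 250 bp bins that meet at the start, 13.7% of the bases lay under a peak, against 30.6% in the bin that begins 1000 bp downstream and 20.5% in the bin that begins 750 bp upstream. The cover at the start was 0.448 times the downstream maximum, and 0.413 times in replicate 1 and 0.462 times in replicate 2. At the 5 kb ends of the profile, 6.45% of bases were covered upstream and 11.3% downstream. Counting every annotated transcript start gave a ratio of 0.560.

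**Figure D1:**
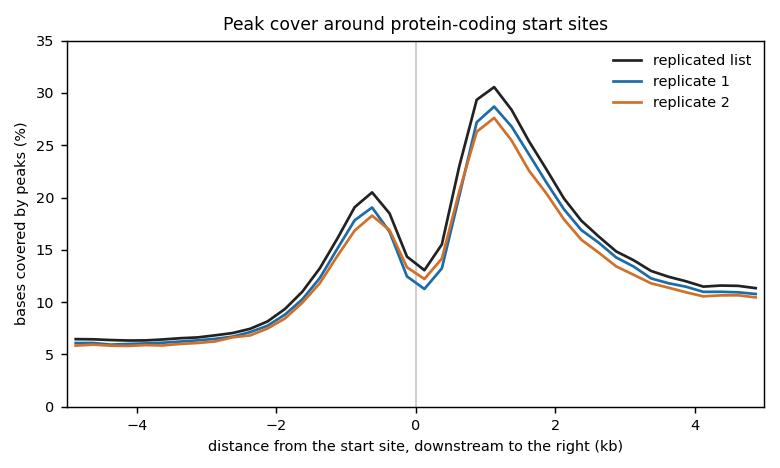
Percent of bases covered by peaks (vertical axis) in 250 bp bins from 5 kb upstream to 5 kb downstream of protein-coding start sites (horizontal axis, kb), with a line each for the replicated list and the 2 replicates. In each list the cover dips at the start site and is highest downstream, at 30.6% in the replicated list.

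Genes that build and run the heart carried the mark over a large part of their surroundings. For each protein-coding gene, the percent of its domain (the gene and 10 kb on both sides) that was covered by peaks was measured, and the median over all genes was 6.07%. Each fixed list of genes was set against 10000 random lists of genes of like domain length, and a list was called high when its median reached the 95 percentile in the replicated list and in both replicates. With 1 peak list taken alone, 2.1 of the 21 gene lists would pass the high or the low threshold by chance, and the joint call can be no more frequent. Of the 8 lists of heart cells and heart functions, 6 were high, and of the 13 other lists 1 was high and 1 was low. With random lists matched on GC content as well as length, 5 of the 8 heart lists were high in the replicated list, and of the 13 others 1 was high and 4 were low. Genes are not replicates, so these percentiles describe the lists and are not p-values.

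The 21 cardiac transcription factors had a median cover of 25.9% (replicates 23.5% ± 0.714, SD, n = 2) at percentile 100, and all 21 were above the median of all genes. The highest was Gata5, with 77.1% of its domain covered (71.3% ± 0.292), followed by Gata4 with 55.5% (51.6% ± 0.0313) and Irx4, a ventricular homeobox factor, with 51.2% (47.4% ± 2.09). Gata4, a zinc finger factor required for heart formation, lies on chromosome 14 from 63198922 to 63271692, and 44 peaks fell in its domain. Tbx5, the T-box factor of the atria and the left ventricle (chromosome 5, 119832668 to 119885219), had 34.7% (32.8% ± 1.39). Hand2, a helix-loop-helix factor of the right ventricle (chromosome 8, 57320983 to 57324633), had 28.4% (25.9% ± 0.957), all of it outside the gene itself. Nkx2-5, an early cardiac homeobox factor (chromosome 17, 26838664 to 26845009), had 20.9%, with 12.7% in replicate 1 and 17.9% in replicate 2. The lowest member, the GATA cofactor Zfpm2, had 8.996%.

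**Figure D2:**
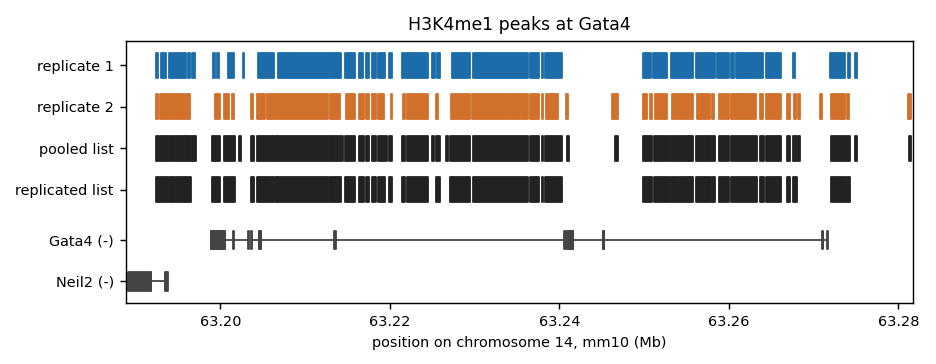
Peaks of each of the 4 lists (filled blocks, 1 row per list) along the Gata4 domain on chromosome 14 (horizontal axis, position in Mb), with the exons (blocks) and extents (lines) of Gata4 and Neil2 below. The replicated list covers 55.5% of the domain, and each replicate's list covers 51.6%.

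The 20 sarcomere genes had the highest median of any list, 37.2% (34.9% ± 2.95) at percentile 100, and 18 of them were above the median of all genes. Cardiac troponin T, Tnnt2 (chromosome 1, 135836354 to 135852260), had 63.6% of its domain covered (59.9% ± 0.224), the atrial light chain Myl7 had 60.6% (57.1% ± 0.754) and the embryonic troponin I gene Tnni1, a neighbour of Tnnt2, had 58.2% (53.5% ± 0.313). The myosin heavy chain Myh6 (chromosome 14, 54941921 to 54966927) had 34.8% (30.2% ± 2.46), in a domain that overlaps 3 other genes. The giant protein gene Ttn was the lowest with 3.45%, over a domain of 298.6 kb. Genes of excitation, calcium handling and natriuretic peptides had a median of 19.3% (17.8% ± 1.63) at percentile 99.93, and 14 of 17 were above the median of all genes. The potassium channel gene Kcnh2 led with 59.1% (54.7% ± 0.427), then the calcium channel gene Cacna1c with 43.8% (40.8% ± 1.14), where 230 peaks lay over 629.2 kb, and the pacemaker channel gene Hcn4 with 42.5% (38.9% ± 3.88). The atrial natriuretic peptide gene Nppa (chromosome 4, 148000722 to 148002079) had 7.61% (8.44% ± 1.22), and the potassium channel gene Kcnd2 was lowest with 0.659%.

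Cardiac signalling genes had a median of 24.9% (23.0% ± 2.20) at percentile 100, with 17 of 21 above the median of all genes. The inhibitory SMAD genes stood highest, Smad6 with 76.5% (72.7% ± 0.485) and Smad7 with 71.7% (68.4% ± 0.938), followed by the ligand gene Bmp7 with 59.96% (53.4% ± 0.149). Bmp10, a ligand of the trabecular myocardium (chromosome 6, 87428994 to 87437677), had 45.4% (42.2% ± 3.40). Nrg1, the endocardial growth factor gene, was lowest with 1.43% of a domain of 1089 kb.

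Lists of the other heart cell types were less covered than these. Genes of endocardium and endothelium had a median of 14.5% (12.8% ± 0.271) at percentile 98.14, with 13 of 15 above the median of all genes, led by Eng with 48.9%, Notch1 with 47.2% and Nfatc1 with 36.0%, and with Emcn lowest at 0.861%. Genes of smooth muscle and pericytes had 15.7% (15.3% ± 0.265) at percentile 98.35, with 8 of 10 above it, led by Cspg4 with 41.3%, Smtn with 36.2% and Pdgfrb with 34.2%, and with Myh11 lowest at 3.07%. Both calls ended when the random lists were matched on GC content too, at percentiles 86.77 and 71.27. Genes of the valves and cushion mesenchyme had 11.99% (10.2% ± 1.15) at percentile 93.98, with 86.22 and 94.52 in replicates 1 and 2, and were not called. They reached 98.05 with that matching. Their highest members were Snai1 with 30.6%, Tgfb2 with 28.2% and Col1a1 with 23.8%, and their lowest was Col3a1 with 0.767%. Genes of the epicardium were not called, with 9.99% (8.50% ± 0.850) at percentile 82.34, from Krt19 with 25.3%, Tcf21 with 16.98% and Wt1 with 14.5% down to Sema3d with 2.17%.

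Outside the heart lists, housekeeping genes were high, with a median of 19.7% (18.6% ± 0.906) at percentile 99.87, from the ribosomal protein gene Rpl13a with 45.6% down to Hprt on the X chromosome with 1.10%. Olfactory receptor genes were low, with a median of 0 at percentile 0, and 1057 of 1134 had no peak base in their domain. When random lists were matched on GC content too, their median was also 0, which left the olfactory list at percentile 50. Those random lists were drawn from genes that included the 1134 olfactory ones. This value therefore does not show whether GC content accounts for the low cover. Limb patterning genes reached 16.8% (13.2% ± 1.46) at percentile 97.725, but the call was not met in replicate 1 (91.465) and the list stood at 41.015 when GC content was matched. The anterior Hox genes, of the A, B and D clusters, were at 11.4% and percentile 86.61. Genes of neurons and neural progenitors were at 7.87% (73.32), of gut, pancreas and lung epithelium at 7.88% (72.75) and of skeletal muscle at 7.28% (57.15).

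The lists of blood, liver, kidney, skin and germ cells lay below the median of the random lists in the main setting, though none was low at the set threshold. Germ cell and macrophage genes crossed that median under alternative settings, given below. Erythroid genes had a median cover of 1.52% at percentile 7.38, with 7 of 16 at 0, among them Alas2, and with Nfe2 highest at 24.0%. Alas2 lies on the X chromosome, where 62.7% of all protein-coding genes were at 0. Liver genes had 2.55% at percentile 9.82, with Alb, the albumin gene, at 0 and Foxa3 at 26.4%. Keratinocyte genes had 1.43% at percentile 13.22, macrophage genes 3.91% at 21.54, kidney genes 4.94% at 31.24 and germ cell genes 3.90% at 33.01. With random lists matched on GC content as well, keratinocyte (2.46), liver (2.425), kidney (1.11) and macrophage (0.43) genes did fall at or below the 5 percentile. Some domains reach into other genes: the macrophage gene Cd68 had 31.2% in its domain, which overlaps 4 other genes, and 0 within the gene itself.

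Among all protein-coding genes, the most covered domain was that of Tcap, which encodes the sarcomere protein telethonin, with 84.4% (77.7% ± 1.72). This domain of 21.1 kb is mostly flank and overlaps 3 other genes, and 88.5% of the Tcap gene itself was covered. Next came Crip2 with 81.2%, the GATA cofactor gene Zfpm1 with 78.0%, Gata5, Trim11 with 76.6%, Smad6, G430095P16Rik with 76.0%, Adamtsl4 with 75.9%, Pnmt with 75.7% and Ahdc1 with 74.7%. Pnmt lies next to Tcap and shares most of its domain. The peaks of highest enrichment were in an intron of Dyrk1a (chromosome 16, 94600748 to 94603795, 10.3-fold), an intron of Ahdc1 (chromosome 4, 133013217 to 133030401, 9.92-fold), an intron of Hdac5 (chromosome 11, 102213389 to 102216586, 9.77-fold), an exon of Luzp1 (chromosome 4, 136546272 to 136549415, 9.69-fold) and an intron of Ccdc85c (chromosome 12, 108255170 to 108258060, 9.64-fold). Joining peaks at most 1 kb apart gave 107067 regions with a median of 0.854 kb, of which 1096 were wider than 10 kb and 175 wider than 20 kb. The widest lay over Shb (chromosome 4, 45434094 to 45523950, 89.9 kb), where 31 peaks covered 89.0% of the region. The next were over Mical2 (74.3 kb), Pitpnm2 (69.7 kb), Zmiz1 (67.5 kb) and Dab2ip (63.1 kb).

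Distal peaks held binding sequences of the MEF2, GATA and TEAD families, which act in heart muscle, more often than matched sequence away from peaks. In 20000 windows of 500 bp at their summits, a consensus was sought and its share was divided by that in control windows of like GC and repeat content, then set against up to 10 scrambles of the same consensus. The MEF2 sequence was in 7.97% of peak windows and 4.54% of control windows, a ratio of 1.76 (scrambles 1.05 to 1.27). The GATA sequence was in 30.2% and 21.7%, a ratio of 1.39 (scrambles up to 1.22), and the TEAD sequence in 16.6% and 12.7%, a ratio of 1.31 (up to 1.02). These 3 were above their scrambles in both replicates' own lists, with ratios of 1.69 and 1.82 for MEF2, 1.34 and 1.34 for GATA, and 1.18 and 1.30 for TEAD in replicates 1 and 2. The FOX sequence, at 1.27, and the NKX2 sequence, at 1.19, were also above all scrambles, which made 5 of the 16 sequences that could be tested, where 1.55 would be high by chance. The other 11 lay within their scrambles. Among them were the TBX sequence at 0.979 and the E-box CAGCTG, of HAND and other factors, at 1.18. The AP-1 sequence at 1.10 and the liver sequence HNF4 at 0.764 were others. The HNF1 and REST sequences had too few matches to test, and the CTCF and nuclear receptor sequences had too few scrambles that could be used. Against 7 scrambles with the same number of CpG, CTCF lay within their range. The FOX call ended in replicate 1's own list (1.11) and against scrambles with the same number of CpG, and the NKX2 call ended for peaks with a −log10 q of at least 2 (1.09). AP-1 was above its scrambles in each replicate's own list (1.11 and 1.16). It was also above them against windows 2 kb away from the same peaks (1.26) and against scrambles with the same number of CpG. The E-box CAGCTG was above its scrambles in the last 2 settings (1.56 and 1.18). The ETS sequence was above its scrambles in the pooled list (1.26). SOX was below its scrambles in replicate 2's own list (0.908) and in windows between peaks (0.7996). PITX was below them against windows 2 kb away (0.623) and above them in windows between peaks (1.19). Against windows 2 kb away the MEF2 ratio was 0.852, though still above its scrambles, whose highest was 0.631. Those windows were not matched on GC content or repeat share. The MEF2 scrambles had a median ratio of 0.520 there, against 1.09 with matched windows, so ratios there also carry differences in composition.

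**Figure D3:**
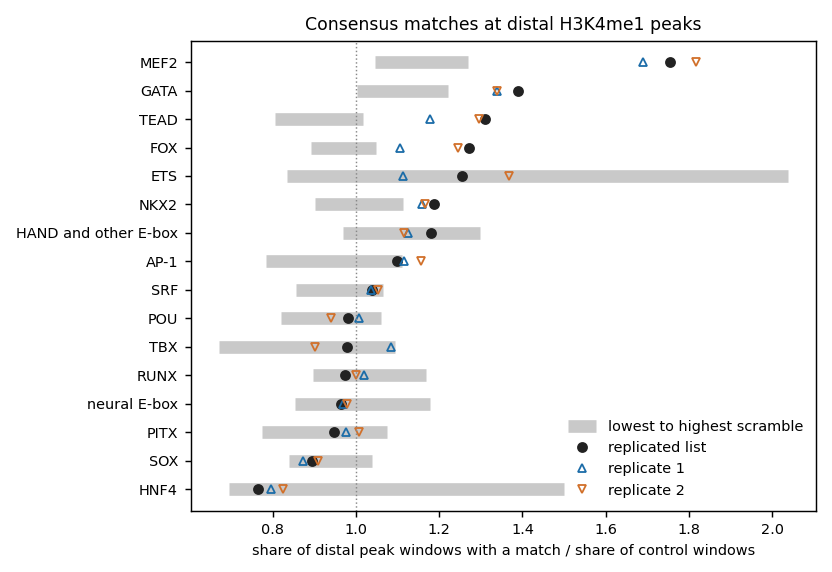
Ratio of the share of distal peak windows to the share of matched control windows that hold each consensus (horizontal axis), with points for the replicated list and each replicate and grey bars for the range of up to 10 scrambles in the replicated list, for the 16 sequences that could be tested. MEF2, at 1.76, lies farthest above its scrambles.

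Chromosomes rich in genes held more marked regions. Across the 19 autosomes the density of peaks ran from 61.1 per Mb on chromosome 14 to 108.2 per Mb on chromosome 11, with a median of 75.9. It rose with the density of protein-coding genes (Pearson r = 0.683, two-sided permutation p = 0.00100, adjusted p = 0.00137 over the 3 lists tested, and Spearman rho = 0.633, p = 0.00449, adjusted p = 0.00449). Without chromosomes 7 and 11, the 2 farthest from the median in gene density, r was 0.776 (p = 0.000230) and rho was 0.723 (p = 0.00152). In the replicates' own lists r was 0.671 and 0.679. Chromosomes of 1 genome are not independent samples, so this relation describes the lists. The X chromosome stood apart with 9.82 peaks per Mb, and with 14.8 and 13.8 in replicates 1 and 2. No peak was called on the Y chromosome, of which 96.3% is repeat sequence.

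**Figure D4:**
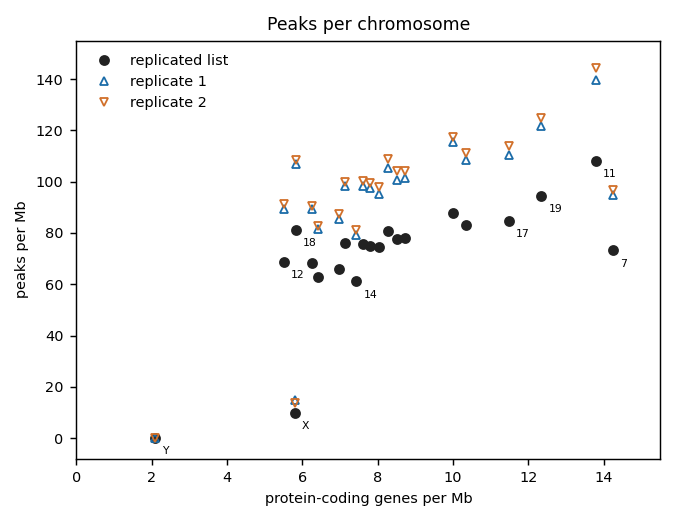
Peaks per Mb (vertical axis) against protein-coding genes per Mb (horizontal axis), with 1 point per chromosome for the replicated list and for each replicate. In the replicated list the 19 autosomes lie between 61.1 and 108.2 peaks per Mb, and X, at 9.82, lies below them all.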

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

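Of 346 alternative values of the main results, 301 kept their direction and their side of the threshold, moved by less than the spread between replicates or, for counts, stayed within 1.5 times the main count, including all 36 for genomic location. For location this means the same direction and side against random placement, whatever the size of the change. For the overlap of the replicates, the spread used was the SD of its 2 directions, 0.896. In gene lists, 242 of 273 did so, and the cardiac transcription factor, sarcomere, excitation, cardiac signalling and housekeeping lists were high under every one of the 13 settings. The settings include each replicate's own list. A high call already required both of these, so for lists called high their outcome was fixed. The scrambles with the same number of CpG and the lists without members whose domains overlap were chosen after seeing the data.

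The mean share of shared peaks was 70.1% for peaks with −log10 q of at least 5, 65.8% when at least 50% of the peak had to overlap, 48.9% when at least 50% of both did, and 66.0% for the 50000 peaks of lowest p in each list. The share of replicated peaks covered in both replicates was 68.1% and 39.7% at −log10 q of at least 2 and 5, 86.3% with 1 bp of overlap and 61.9% with at least 50% of both peaks. These rules and thresholds leave fewer (or, at 1 bp, more) peaks that can count. Promoter minus intergenic enrichment was 0.280 in the pooled list, 0.137 at −log10 q of at least 5, 0.273 with promoters of 2.5 kb, and 0.162 to 0.195 when either replicate was left out. Cover at the start site over the downstream maximum was 0.560 with every transcript start, and 0.413 to 0.462 when either replicate was left out.

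With random lists matched on length and GC content, the lists stood at 86.77 (endothelium), 71.27 (smooth muscle), 98.05 (valves), 41.015 (limb patterning, reversed), 50 (olfactory receptors), 0.43 (macrophage), 1.11 (kidney), 2.425 (liver) and 2.46 (keratinocyte). Lists that were neither high nor low crossed the median of the random lists in 12 cases. These were skeletal muscle at 47.35 to 48.92 when either replicate was left out, 14.89 with 50 kb flanks, 33.12 with GC matching and 45.75 on autosomes alone, and neurons at 20.58 with 50 kb flanks, 39.42 by peaks per 10 kb and 41.29 without members whose domains overlap. The others were epicardium at 45.09 and germ cells at 79.29 with 50 kb flanks, gut, pancreas and lung at 27.325 with GC matching, and macrophages at 71.94 without members whose domains overlap. Limb patterning was at 91.465 to 96.465 when either replicate was left out, 87.65 at −log10 q of at least 5, 82.375 with 50 kb flanks and 94.935 by peaks per 10 kb. Valve genes were at 97.61 and keratinocyte genes at 3.06 at −log10 q of at least 5. Valve genes were at 95.02 by peaks per 10 kb, but at 86.22 to 94.52 when either replicate was left out. Epicardial genes were at 95.445 by peaks per 10 kb, liver genes at 3.945 over gene bodies alone, and erythroid genes at 3.22 with no matching. Apart from these rules of overlap, the cause was not tested. Of 216 alternative values of single genes, 145 moved by more than the spread between replicates, and of 143 for single motifs 129 kept their call. For GATA, MEF2, TEAD, TBX and NKX2, the scrambles with the same number of CpG gave the same values as the main setting. That alternative therefore adds no separate check for them. Since the depth was unknown, whether weak regions missing from 1 replicate lacked the mark or lacked reads was not testable.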

Other observations

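The tests of gene density on X and of the share of cardiomyocytes were chosen after the result was seen, and so were the genes named here on X and the comparison of transcription factors with other genes.

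The X chromosome held 1606 replicated peaks, and 594 of its 948 protein-coding genes (62.7%) had no peak base in their domain, against 19.6% of autosomal genes. The marked X-linked genes were led by Bcor, a transcriptional corepressor gene, with 35.6% of its domain covered (33.4% ± 0.794, SD, n = 2), then Elf4 with 25.6% (22.9% ± 0.382), Rtl5 with 23.2%, and Srpk3, a muscle kinase gene, with 22.8% (19.9% ± 0.640).

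Some gene lists differed between the replicates. Of 20 sarcomere genes, 17 were more covered in replicate 1, with a median of 37.0% against 32.8% in replicate 2. Of 15 valve and cushion genes, 10 were more covered in replicate 2, with medians of 9.39% and 11.01%. The differences of 8 of the 21 lists lay past the 5 or 95 percentile of random lists of like length, where 2.1 would by chance. Sarcomere genes (0.03) and genes of excitation, calcium handling and natriuretic peptides (2.17) were toward replicate 1. Genes of the valves (99.75), cardiac transcription factors (99.61), limb patterning (99.48), anterior Hox (99.28), macrophages (97.71) and neurons (96.13) were toward replicate 2. These directions are relative to random lists, and not every list had most members on 1 side. Of 21 cardiac transcription factors, 11 were more covered in replicate 2 and 10 in replicate 1. For neurons the counts were 10 and 8, and for excitation 7 and 10. They were more one-sided for limb patterning (9 and 2), anterior Hox (9 and 3) and macrophages (10 and 3). Against random lists matched on length and cover, 4 lists were past a threshold, all toward replicate 2: valves, macrophages (96.97), anterior Hox (95.73) and limb patterning (95.685). Against lists matched on length and GC content 6 were, without limb patterning (88.525) and macrophages (88.32).

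The low density of peaks on X was weighed against repeats and gene density. X had 18.4 peaks per Mb outside repeats, below the lowest autosome (93.7), so its repeat content does not account for it. X-linked genes had a median cover of 0, against 1.67% for autosomal genes of like length and GC content, and the 5 percentile of those was 1.35%, so gene density does not account for it either. A lower copy number of X in pooled male and female tissue may contribute, and X peaks had a median of 2.97-fold against 3.16-fold on autosomes. Without read counts or the sex ratio of the pools, that cannot be told apart from a lower level of the mark on X.

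Part of the differences between the replicates may follow from the breadth of the marked regions in broadly covered genes. Against random lists matched on length and GC content the sarcomere difference stayed at percentile 0.15 and the valve difference at 99.76, so GC content does not account for these. Against lists matched on length and cover the sarcomere list stood at 5.35, just inside the 5 to 95 percentile range, with excitation at 24.205, cardiac transcription factors at 93.88 and neurons at 85.27, so breadth may account for these, while the valve list stayed outside at 98.3. A larger share of cardiomyocytes in the tissue of replicate 1 would move the lists of all 4 other heart cell types toward replicate 2. This shared shift was not seen. Against random lists matched on length, valves (99.75) and smooth muscle (90.65) lay toward replicate 2, but endothelium (13.66) and epicardium (26.23) toward replicate 1. Of these lists only the valves were past a threshold, and the gap between the lowest and highest was at percentile 94.53 among random lists. The test therefore cannot decide on the share of cardiomyocytes, and the sarcomere difference alone cannot tell it apart from breadth. The input file named for replicate 1 and not for replicate 2, and true differences between the embryos, were not tested.

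Within the lists of other tissues, genes of transcription factors had more cover than the other members. Their median was 13.8% for 44 factors against 3.03% for 99 others, a difference of 10.8 percentage points (two-sided permutation p = 2.0e-05, adjusted p = 0.000180 over the 9 tests made, and p = 0.000150 and 6.0e-05 in replicates 1 and 2). It was 11.2 points among members whose domain overlaps no other protein-coding gene (permutation p = 0.000130, adjusted p = 0.000270, 20 against 37). Protein-coding genes that reach into the domain therefore do not account for it. Peaks tied to genes farther away, or to noncoding genes in the domain, were not excluded. Ranked among genes of like length and GC content, factors were 19.2 percentile points higher (permutation p = 0.0102, adjusted p = 0.0132), with p = 0.103 in replicate 1 and 0.0426 in replicate 2, so the replicates left GC content and length open. Genes are not replicates and some share domains, so these p-values describe the lists. The comparison was also chosen after the result was seen. No biological explanation was tested, since the series holds no other tissue.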
